A study of Homo sapiens with 2 samples.

How the data were processed

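The measurements were promoter-array profiles of chromatin from SW480, an established human colon carcinoma cell line. The growth protocol in the labels also describes HEK293T, a kidney cell line, while the characteristics and the extraction protocol of both samples name SW480 alone. Per the labels' protocols, cells were fixed with formaldehyde, the chromatin was sheared by sonication, and DNA was recovered by immunoprecipitation (IP). The EBP50 IP, made with a custom rabbit antibody against a peptide of the EBP50 C-terminus, carried Cy5. The control DNA carried Cy3. The labels disagree on that control: the source name and labelling protocol call it a mock IP with a control antibody, while the characteristics call it input DNA with no antibody. It is called the mock IP here. Each of the 2 samples was hybridised to a different array of a 2-array promoter set, so the samples cover different promoters and each was measured once. No dye swap and no replicate hybridisation was given, and the labels do not say whether both arrays received DNA of the same IP.

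The deposited scanner files hold spot intensities. Per the file headers, Agilent Feature Extraction subtracted the background, detrended the signals across the array, and multiplied each channel by 1 linear dye factor, with no lowess fit. The version is 10.1.1.1 per the submitters' processing notes. Signals that did not pass the background were replaced by a small positive surrogate, per the file headers. The deposited log10 ratio (Cy5 over Cy3) was set to 0 by that software for 23.6% of promoter probes on array 1 and 18.6% on array 2, and it was used here only through its sign. The deposited p-value of each spot comes from the same software's error model and does not measure variation between IPs. The deposited error score of each log ratio was not used further. The authors' deposited value tables hold log2 ratios of Cy5 over Cy3 without centring. Their medians were 0.195 and 0.153, and each value lay within 0.005 of the log2 ratio recomputed from the scanner signals, so scale, centring and direction were all settled by this comparison. The genome build of the probe coordinates is not given in the sources used here.

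The processed intensities were turned into log2(Cy5/Cy3) and each array was centred on the median of its promoter probes. Control features (6284 per array), probes with no position (12 and 7) and probes marked as outliers (23 and 26) were left out. This left 237175 probes on array 1 and 237168 on array 2, of 44 to 60 bases, with centres a median of 177 and 178 bp apart. A probe is called lit in a channel where the scanner software marked it as well above background. Counts of regions among probes lit in both channels used those probes alone, centred anew on their own median. The window value of a probe is the mean centred log2 ratio of all probes with centres within 500 bp, given at least 3 probes. An enriched region is a run of at least 3 probes with window values of at least 1 (2-fold), with neighbours at most 1000 bp apart. A mirror region is found by the same rule with the sign turned, and serves as the background measured the same way on the side of the mock IP. The rules were fixed before the data were examined, as were the windows to name: the 25 highest windows with every probe above 0 and the 5 lowest windows by the mirrored rule, 1 per region. They were written for genes. Because the files used here pair no probe with a gene and the coordinates have no stated build, they were applied to windows, and positions are printed as the files give them.

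With 1 array per promoter set there is no replicate, so no test across samples was possible and no p-value for enrichment is given. The precision is limited by this number of arrays. An SD beside a window is the spread over the neighbouring probes in it. Where the mock signal of a probe was not well above background, it was set to the lowest Cy3 signal that was, 104 units on array 1 and 103 units on array 2. Its own signal was kept where that was higher. This gave a lower bound on the fold, averaged on the log2 scale over the probes of the window that were lit in Cy5. It holds for those probes and not for the whole window. Unlit spots can lie above the lowest lit signal, so it is not a strict limit. This bound is open to dye bias. Counts of regions were set against 100 shuffles of the log ratios among probes of the same array and of similar brightness (20 strata), which keep the distribution of single probes and remove the order along the chromosome. For the spacing of regions, a test added after seeing the data, the threshold was moved in each shuffle until it held about as many regions as were observed (to within 2 regions). Runs of probes lit in only 1 channel were set against 100 shuffles among probes of the same length. Intervals on regions per 1000 probes are exact 95% binomial intervals and cover counting error only. Relations across chromosomes were tested with 100000 permutations, two-sided.

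The region rule was checked on simulated data in which 200 windows of the shuffled log ratios of each array were raised by known amounts. On array 1 (237175 probes) 28% of windows raised 2-fold were found, 86% of those raised 4-fold and 100% of those raised 8-fold. On array 2 (237168 probes) the shares were 29%, 87% and 99%. Regions near the threshold are therefore found only in part. The amounts were added to log ratios of all probes, of which 44.6% on array 1 and 37.8% on array 2 were lit in neither channel. Signals lost below background were not simulated. The shares therefore describe the rule, and true changes on these arrays may be found less often. Windows of 3 or 4 probes, which the region rule accepts, were not among those raised, so the shares do not cover them.

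The alternatives were normexp background correction with an offset of 50 (limma 3.58.1 in R 4.3.3; on median spot signals, in place of the mean signals planned), loess within each array, the deposited value tables, lit probes alone, outlier-marked spots kept, saturated spots left out, other windows, thresholds and run lengths, the scanner software p of 0.01 for each probe, and removal of the running median over brightness. Centring on lit probes, a bound for each dim channel, removal of the median of each probe length, and leaving out chromosome Y were added after seeing the data. The setting with the bound left out probes lit in neither channel and centred the rest anew. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for all other steps, and matplotlib 3.10.9 for the plots. The medians of 18 planned gene lists, the scores of genes by symbol, the share of regions with a TCF/LEF motif and every step that needs the GC content of probes were not run, since they need gene names or probe sequences that were not used here.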

Results

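EBP50 (gene symbol SLC9A3R1) is a scaffold protein with PDZ domains that links membrane proteins to ezrin and the actin skeleton. ChIP-on-chip was used to find where along human promoters DNA was recovered with an EBP50 antibody in SW480 colon carcinoma cells, and the series' title frames the aim as mapping EBP50 binding motifs. The EBP50 IP (Cy5) and the mock IP (Cy3) of SW480 chromatin were compared on 2 promoter arrays, 1 hybridisation each. Array 1 held chromosomes 1 to 9 and part of chromosome 10, and array 2 held the rest of chromosome 10 and chromosomes 11 to 22, X and Y. Signals were low. The median background-subtracted signal was 14.3 units in Cy5 and 11.2 units in Cy3 on array 1, against local backgrounds of 96.5 and 24 units, and 26.9 and 18.8 units on array 2, against 104 and 27.5 units. Of the probes, 41.4% on array 1 and 48.1% on array 2 were lit (well above background) in both channels, and 44.6% and 37.8% were lit in neither.

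The first question was which promoter segments were richer in the EBP50 IP than in the mock IP. On array 1, 960 regions had windows at least 2-fold richer in the EBP50 IP, and 1004 on array 2. Windows reach past a region, and the mean over the region's own probes was below 2-fold in 44 regions on array 1 and 41 on array 2, with 6 and 1 of these on the side of the mock IP. With each dim channel set to its bound, probes lit in neither channel left out and the rest centred anew, 608 and 627 regions were found. The 960 and 1004 regions were short, with a median width of 494 bp on array 1 and 518 bp on array 2 and a median of 4 probes on each. Shuffled log ratios gave a median of 650 regions on array 1, with 712 at most, and 700 on array 2, with 749 at most. Regions whose highest window reached 8-fold numbered 36 and 43, against at most 11 in the shuffles of either array. Among probes lit in both channels, 2 regions on array 1 and 1 on array 2 reached 8-fold, within the range of the shuffles (0 to 2 on each). Enriched regions did not lie closer together than the same number of regions in shuffled data on array 1, where 108 had another within 20 kb, against a median of 114.5 in the shuffles. On array 2, 168 did, against a median of 136, and 1 of 100 shuffles reached as many. Without chromosome Y it was 141, which 29 of 100 shuffles reached. Among probes lit in both channels, 6 regions on array 1 (a median of 6 in the shuffles) and 29 on array 2 (2 to 24 in the shuffles) had another within 20 kb, and 10 on array 2 without chromosome Y, which 36 of 100 shuffles reached.

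Depletion by the same rule was more frequent. Mirror regions, with windows at least 2-fold richer in the mock IP, numbered 4012 on array 1 and 3947 on array 2, which is 4.18 and 3.93 times the enriched regions, and those reaching 8-fold numbered 189 and 203. Enriched regions made up 19.3% of all regions on array 1 and 20.3% on array 2. Other scalings moved this share: it was 36.4% and 34.9% after loess, 31.9% and 28.0% when centred on lit probes, 43.4% and 40.9% after removing the trend with brightness, and 86.0% and 100% after normexp. The shares after normexp rose because mirror regions fell to 25 and 0, while enriched regions fell as well, to 153 and 807. Among probes lit in both channels, where both signals were measured, enriched regions fell to 186 on array 1 and 235 on array 2, and mirror regions to 290 and 360. The 186 enriched regions on array 1 lay within the range of the shuffles (163 to 217), the 235 on array 2 lay above it (156 to 220), and 209 of those on array 2 lay off chromosome Y, where the shuffles had a median of 184.5 and 2 of 100 reached 209 or more.

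**Figure D1:**
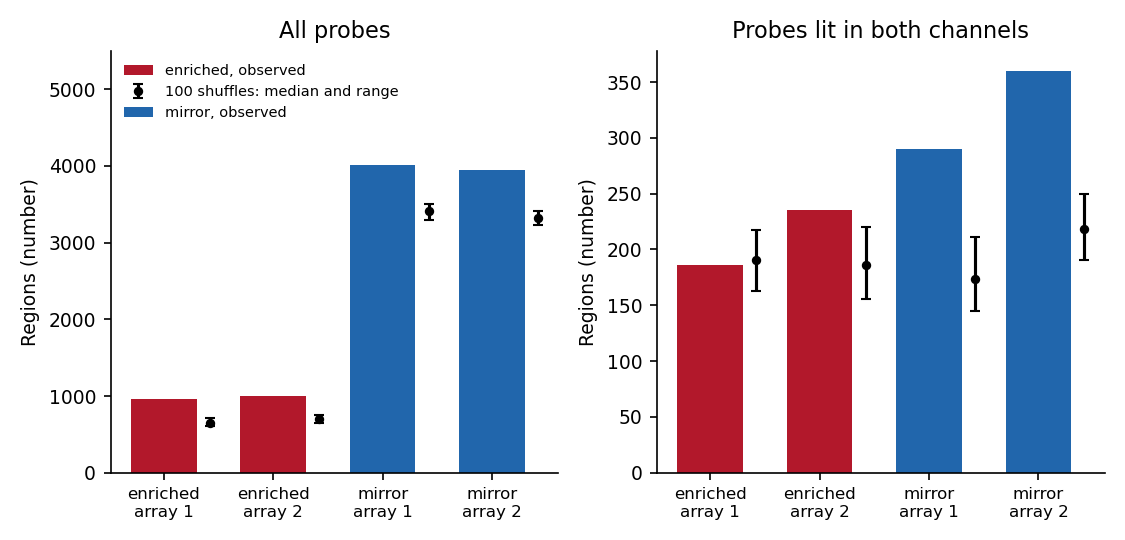
Number of enriched (red) and mirror (blue) regions on each array, for all probes (left) and for probes lit, that is well above background, in both channels (right), with the median and range of 100 shuffles as black points and bars. With all probes every count lies above its shuffles, and with lit probes the 186 enriched regions of array 1 lie within theirs.

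The next question was which positions carried the highest ratios. The 25 highest windows had centred log2 ratios of 3.65 to 5.22 and lay on 14 chromosomes, 12 of them on array 1 and 13 on array 2. In 20 of them no probe was lit in the mock IP, in 6 every probe was lit in the EBP50 IP, and in 0 were all probes lit in both channels. Over the probes of each window that were lit in the EBP50 IP, and with the mock signal set to its bound, the EBP50 IP exceeded the mock IP by at least 4.40-fold to at least 36.5-fold. These bounds leave out probes not lit in the EBP50 IP, so they hold for a whole window only where every probe was lit in it. Where the mock signal was not well above background, a log2 ratio and its SD are nominal values, and the bound is the value to read. The spread between neighbouring probes was large in most of them, because a pair of strongly lit probes often stood beside a probe lit in neither channel. Such a probe could still pass the rule that every probe lie above 0. In the chromosome 3 window from 44747008, the probe lit in neither channel had a log2 ratio of 0.42 at 32.1 units of Cy5. The rule was therefore no check on probes lit in neither channel, and it may have been easier to pass on the side of the EBP50 IP. Shuffles reached a window as high as the top of array 1 in 3 of 100 draws and as high as the top of array 2 in 1 of 100.

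The window with the most probes lay on chromosome 6 from 47853659 to 47854461 on array 1. Its mean log2 ratio was 4.62 ± 0.80 (SD over 6 probes), with single probes between 3.72 and 5.87. All 6 probes were lit in the EBP50 IP alone, at 510 to 1415 units, while the mock signals were 21.1 to 56.5 units and not well above background, so the difference was at least 6.95-fold. The next probe upstream, from 47853446, was also lit in the EBP50 IP alone, which made this the longest such run on array 1, at 7 probes. Chromosome 3 carried 3 of the highest windows. The window from 36394166 to 36394519 had a log2 ratio of 4.61 ± 1.74 (SD over 3 probes, at least 10.0-fold), and the window from 166282693 to 166283234 had 3.83 ± 0.93 (SD over 3 probes, at least 4.40-fold). In both, every probe was lit in the EBP50 IP alone. The window from 44747008 to 44747389 on the same chromosome held 3 such probes and 1 probe lit in neither channel, with a log2 ratio of 4.06 ± 2.57 (SD over 4 probes, at least 8.17-fold over 3 lit probes).

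**Figure D2:**
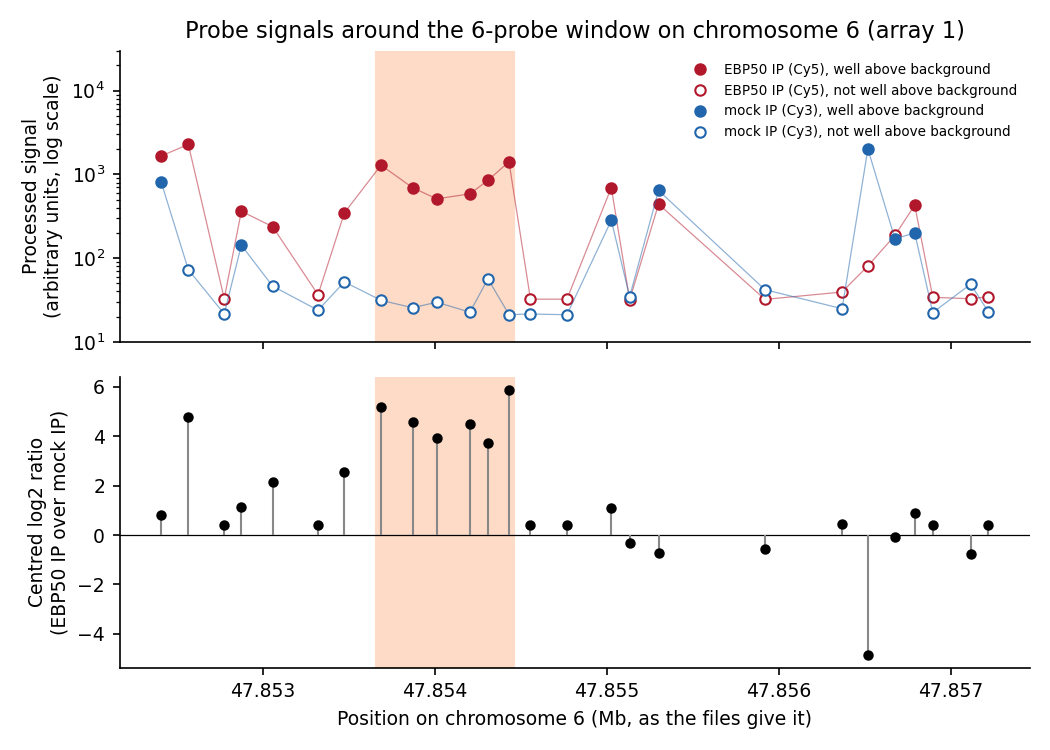
Processed signals of single probes (top, log axis) and centred log2 ratios (bottom) around the chromosome 6 window from 47853659 to 47854461, shaded; filled points are well above background and open points are not. Inside the window the EBP50 IP lies between 510 and 1415 units, and no mock signal exceeds 56.5 units.

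The order of the windows is that of the log2 ratios, which are nominal where the mock signal was not well above background, and the bounds do not all follow it. On array 2, windows off chromosome Y included chromosome 15 from 87681431 to 87682105, with a log2 ratio of 4.59 ± 3.78 (SD over 3 probes, at least 34.1-fold over 2 lit probes), and chromosome 20 from 2797189 to 2797716, with 4.20 ± 2.70 (SD over 4 probes). The 3 probes of the chromosome 20 window lit in the EBP50 IP differed at least 11.9-fold. By this bound the windows on chromosome 16 from 70305843 and chromosome 13 from 28958144 stood higher, at least 14.4-fold and at least 12.3-fold. Chromosome Y held 8 of the 25 windows. Of these, 4 had the same probe lengths and the same spacing between probes as each other, and 2 others shared a second layout. The highest of them, from 9977466 to 9977982, had a log2 ratio of 5.22 ± 3.20 (SD over 3 probes, at least 36.5-fold over 2 lit probes). On the side of the mock IP, the 5 lowest windows ranged from -5.22 on chromosome 21 (42944998 to 42945535) to -4.63 on chromosome 7 (91602353 to 91602821). The window with the most probes among them lay on chromosome X from 1342612 to 1343477, at -5.04 ± 1.26 (SD over 8 probes), with all 8 probes lit in the mock IP alone and a difference of at least 7.63-fold. Under normexp all 30 windows moved toward 0, to sizes between 0.26 and 1.97, and 8 fell below 2-fold. The chromosome 6 window from 47853659 stood at 1.27 and the chromosome 15 window at 1.30, both still past 2-fold, while the chromosome 20 window stood at 0.58, the chromosome 21 window at -0.43 and the chromosome X window at -0.26. The sign of each was the same.

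Promoter segments detected in the EBP50 IP and not in the mock IP were then counted directly, a comparison chosen after the data were examined. Runs of at least 3 neighbouring probes lit in the EBP50 IP alone numbered 21 on array 1 and 24 on array 2, against at most 9 and 11 in shuffles among probes of the same length. These 45 runs lay on 17 chromosomes, and 39 overlapped an enriched region. Every run differed at least 2.31-fold with the mock signal at its bound, with a median of at least 4.82-fold. Chromosome 6 from 152166549 to 152167113 had 4 such probes, with a mean log2 ratio of 4.45 ± 1.16 (SD over 4 probes, at least 7.16-fold). Chromosome 11 from 74478982 to 74479277 had 3, with 5.35 ± 1.04 (SD over 3 probes, at least 8.67-fold), and chromosome 10 from 62886993 to 62887968 had 3, with 5.01 ± 1.00 (SD over 3 probes, at least 7.91-fold). The reverse case was more common: 669 and 597 runs were lit in the mock IP alone, against at most 338 and 353 in the shuffles.

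Enriched regions were spread over all chromosomes. Array 1 gave between 3.54 regions per 1000 probes on chromosome 9 (95% interval 2.75 to 4.49) and 4.97 on chromosome 4 (4.03 to 6.06). Array 2 gave between 2.69 on chromosome 22 (1.80 to 3.86) and 6.34 on chromosome 18 (4.65 to 8.45), apart from chromosome Y. Chromosome Y had 36 regions among 1789 probes, 20.1 per 1000 (14.1 to 27.8). That interval counts its regions as separate, which the shared probe layouts on this chromosome leave open. Chromosome X had 3.10 per 1000 (2.38 to 3.96). The part of chromosome 10 on array 1 gave 4.37 per 1000 (2.80 to 6.49) and the part on array 2 gave 5.36 (4.21 to 6.74), within each other's intervals.

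**Figure D3:**
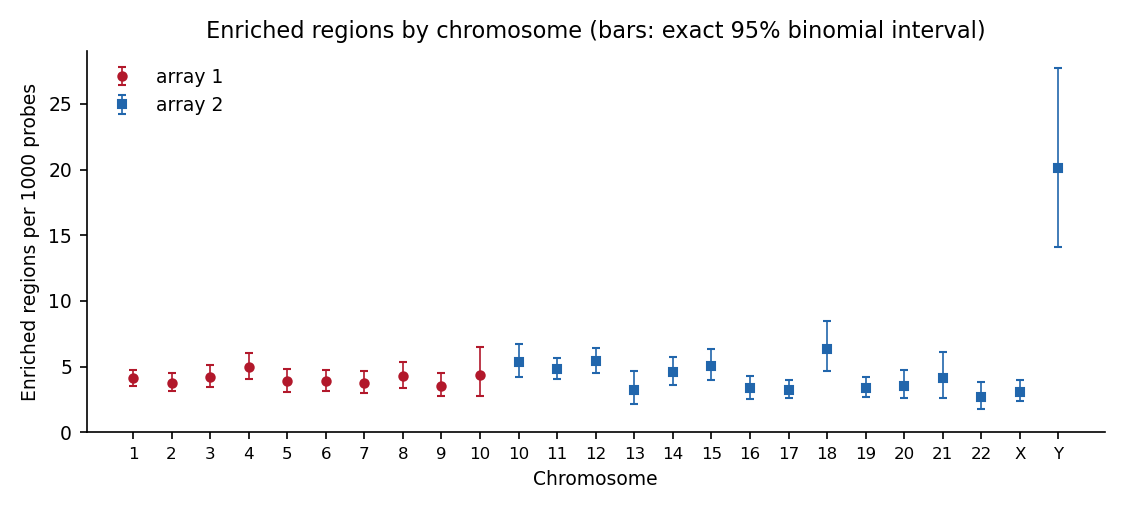
Enriched regions per 1000 probes on each chromosome, array 1 in red circles and array 2 in blue squares, with exact 95% binomial intervals as bars. Chromosome Y stands at 20.1 per 1000 probes, and all other chromosomes lie between 2.69 and 6.34.

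The spread of the log ratios sets the scale for these values. The centred log2 ratio had an SD of 1.30 on array 1 and 1.31 on array 2, and 0.90 and 0.89 among probes lit in both channels. Replicate spots of 1 control probe within an array varied far less, with a median SD of 0.089 on array 1 and 0.070 on array 2 (21 probes, 234 spots on each). These were control probes with at least 4 spots, all lit in both channels, so the value does not cover dim probes. The scanner software's error model put 25511 probes of array 1 and 28776 of array 2 past p of 0.01 with Cy5 higher, and 33480 and 36516 with Cy3 higher. Neighbouring promoter probes agreed most at short range. Among probes lit in both channels, the correlation across probe pairs 60 to 100 bp apart was r = 0.240 on array 1 (95% interval 0.178 to 0.299) and 0.161 on array 2 (0.110 to 0.211), and at 250 to 400 bp it was 0.016 and 0.017. At 600 to 1000 bp it was 0.00655 (-0.00017 to 0.0133) and 0.00981 (0.00377 to 0.0159), and among all probes it was 0.0180 (0.0146 to 0.0213) and 0.0231 (0.0197 to 0.0265). Probe pairs are not independent replicates.

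**Figure D4:**
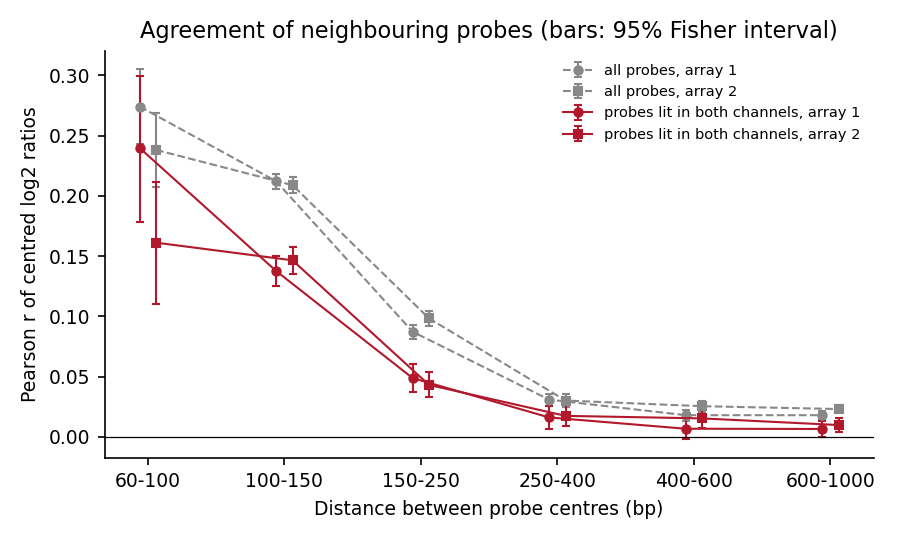
Pearson correlation of centred log2 ratios between probes of one array against the distance of their centres in bp, for all probes (grey, dashed) and probes lit in both channels (red), array 1 as circles and array 2 as squares, with 95% Fisher intervals. Among probes lit in both channels the correlation falls from 0.240 and 0.161 at 60 to 100 bp to 0.016 and 0.017 at 250 to 400 bp.

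The arrays share 3749 control probes, which gave the only sequences measured on both. Of these, 1963 were lit in both channels on both arrays. Across these probes the log2 ratios of the arrays correlated with r = 0.963 and rho = 0.947, and their difference had an SD of 0.214, against an SD of 0.77 on array 1 and 0.80 on array 2. Of the 269 control probes past 2-fold on array 1, 0 had the other sign on array 2.

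**Figure D5:**
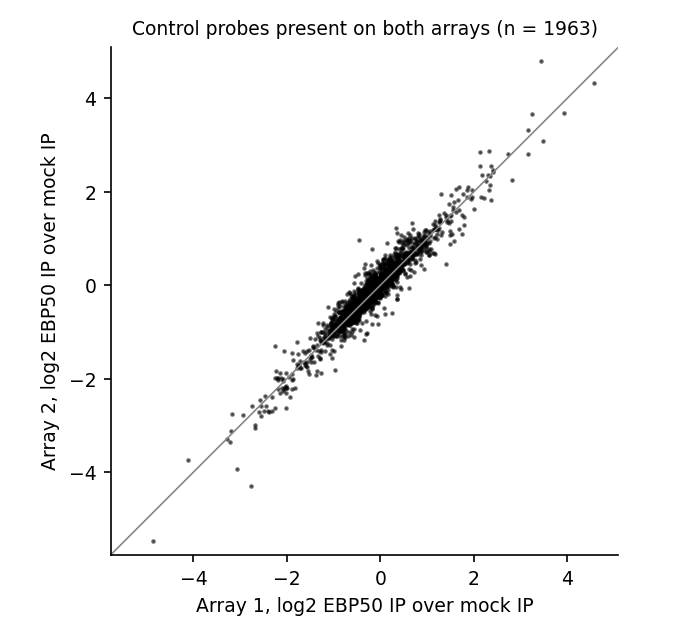
Centred log2 ratio of EBP50 IP over mock IP of 1963 control probes, lit in both channels on both arrays, on array 1 (horizontal) against array 2 (vertical); each point is a probe and the line marks equal values. The points follow the line with r = 0.963.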

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

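Apart from the count of regions reaching 8-fold among all probes, the tests of the number and spacing of regions, the mirror regions, the shared control probes, the amplified fragments and the bound segments were chosen after the result was seen. Control probes were outside the promoter comparison and still carried unequal signals in the channels, with IP and dye not separable without a dye swap: 86 were at least 2-fold higher in the EBP50 IP on both arrays, and 136 were at least 2-fold higher in the mock IP on both. The highest mean over the arrays was that of LACC:SRN_30080, at log2 ratios of 4.58 and 4.33. A promoter probe without a position, A_17_P15137509 on array 1, was lit in the EBP50 IP alone, with a nominal log2 ratio of 5.57 and a difference of at least 39.0-fold with the mock signal at its bound.

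Enriched regions exceeded chance alignment when all probes were used: 960 on array 1 and 1004 on array 2, with 36 and 43 reaching 8-fold, and 21 and 24 runs lit in the EBP50 IP alone, all above the highest of 100 shuffles. This argues against chance alignment of single probes for those counts. Chance stayed open for their spacing (108 and 168 within 20 kb of another, reached by 76 and 1 of 100 shuffles with as many regions) and, among probes lit in both channels, for the 186 regions and 6 neighbours on array 1 and the 2 and 1 that reached 8-fold. The 235 lit-probe regions on array 2, and the 29 of them within 20 kb of another, exceeded all shuffles, but the 209 off chromosome Y were reached by 2 of 100. In a separate run with chromosome Y left out and centring anew, 10 of 210 regions had such a neighbour, which 36 of 100 shuffles reached. Whether EBP50 binding may lie behind the excess is open, since mirror regions, which EBP50 binding does not predict, exceeded their shuffles too.

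Mirror regions outnumbered enriched regions, and IP signals lost below the higher Cy5 background are a candidate explanation that stayed open. The ratio fell from 4.18 to 1.56 on array 1 and from 3.93 to 1.53 on array 2 when only probes lit in both channels were used. This fall decides nothing, because the filter itself removed 27170 probes lit in Cy3 only against 5954 lit in Cy5 only on array 1, and 27343 against 6196 on array 2, so true depletion in the IP would give it as well. The lit-probe counts were also centred anew on the lit probes. That centring alone, with all probes kept, took the ratio to 2.14 on array 1 and 2.57 on array 2. With normexp mirror regions fell to 25 and 0 and enriched regions to 153 and 807, for a cause that was not tested. A larger or more even mock DNA pool was not tested.

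Log ratios scattered widely between probes and agreed between neighbours most at short range. Measurement noise as the cause of the scatter was examined with the shared control probes lit in both channels, which correlated between arrays with r = 0.963. This argues against noise for lit probes, though promoter probes had no such repeat. For probes not lit in both channels, noise stays open. A bias that follows brightness or probe length is argued against by the correlation at 60 to 100 bp, of which a share of at least 1.00 was left on each array after removing both (0.240 and 0.166), and EBP50-bound segments as the whole cause by the mirror regions among lit probes, which were at least 1.37 times the highest of their shuffles. Few amplified DNA fragments in either pool may be a source: at 250 to 400 bp the uncorrected correlation was at most 0.017 among lit probes, and 0.031 and 0.030 among all probes, as short fragments would give, though 0.0180 and 0.0231 were left among all probes at 600 to 1000 bp. Whether short bound sites could give the same fall was not tested. A dye preference of single probe sequences was not tested either, since there was no dye swap.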

How the results depend on the processing

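The alternatives named as added in the processing section were chosen after seeing the data. No paired analysis was possible because each promoter array was hybridised once. Numbers of regions moved by over 1.5 times under most rules, and mirror regions outnumbered enriched ones under all of them except normexp, where the cause of the turn was not tested. Normexp was also the only setting that used spot signals without the dye factor and the detrending. In the order enriched on array 1, enriched on array 2, mirror on array 1 and mirror on array 2, the counts were 960, 1004, 4012 and 3947 by the main rule. They were 153, 807, 25 and 0 with normexp, 1446, 1449, 2530 and 2699 with loess, and 186, 235, 290 and 360 with probes lit in both channels. They were 450, 497, 2459 and 2501 with a window of 1000 bp, 313, 388, 2342 and 2299 with the window median, 2882, 2990, 8093 and 8033 at 1.5-fold, and 206, 250, 1255 and 1266 at 3-fold. They were 492, 566, 2672 and 2550 with at least 4 probes, 102, 149, 880 and 971 with the scanner software p for every probe, 1708, 1689, 2228 and 2438 with the brightness trend removed, and 608, 627, 1179 and 1396 with each dim channel at its bound. A changed threshold or run length explains the counts at those settings by construction. Fewer probes alone do not explain the counts for lit probes. There the ratio of mirror to enriched regions fell from 4.18 to 1.56 on array 1 and from 3.93 to 1.53 on array 2. That filter removed more probes lit in Cy3 only than in Cy5 only, and the lit probes were centred anew. The cause was not tested for the other settings. The SD of the log ratios was 0.54 on array 1 and 0.53 on array 2 with normexp, and 0.89 to 1.32 under the other settings for which it was computed. It was not computed with the brightness trend removed, with centring on lit probes or without chromosome Y. The value tables, outlier-marked spots kept in, a 250 bp window, removal of probe-length medians, centring on lit probes and leaving out chromosome Y kept every count within 1.5 times. The 250 bp window needed only 2 probes in place of 3, so its width was not changed alone. No promoter spot was saturated, so leaving saturated spots out moved nothing. Of 292 values of the 30 named windows under alternatives, 198 moved by over 0.01 on the log2 scale, 23 of them by more than the SD over probes (18 with normexp, 5 with a 1000 bp window), and 0 changed sign. That SD is wide, and moves within it were large: the median move was 3.07 with normexp and 1.60 with a 1000 bp window, which took the chromosome 6 window from 87698922 from 3.70 to 1.16. With normexp 8 windows fell below 2-fold. At 250 bp 8 windows, the 3 highest among them, had too few probes for a value. With lit probes alone no named window kept 3 probes. The GC, gene list and motif alternatives were not run. Signal over background limits all counts: a segment not lit in a channel has only a bound there.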

Other observations

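Chromosome Y stood apart from the other chromosomes. Besides 8 of the 25 highest windows it held 6 of the 45 runs lit in the EBP50 IP alone, among them chromosome Y from 9293113 to 9293729 and from 9931959 to 9932575, with differences of at least 12.9-fold and 12.3-fold with the mock signal at its bound. The median log2 ratio of chromosome Y probes lit in both channels was 0.19, and that of every other chromosome on either array lay below 0. Centring was on all probes, which put the median of all lit probes at -0.150 on array 1 and -0.098 on array 2. The sign on the other chromosomes follows from that centring. Among the 8 windows, the 4 that shared a layout also had near-equal highest Cy5 signals, between 4793 and 5415 units. The 2 with the second layout had 4495 and 4394 units. The window from 9936871 to 9937387 was counted in neither layout. It had the same width of 517 bp as the 4 of the first layout, with a highest Cy5 signal of 5548 units. Probe sequences were not used here, so whether windows with the same probe spacing are copies of 1 sequence was not tested. The windows, runs and regions of chromosome Y may therefore not be separate events. Without chromosome Y, 974 enriched regions were found on array 2 after centring anew.

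Chromosomes with more probes not lit in both channels gave more enriched regions per 1000 probes, a hypothesis written down before the test. Over 23 chromosomes without Y, Spearman's rho was 0.42 (permutation p = 0.0467, Benjamini-Hochberg adjusted p = 0.07 over 6 relations) and Pearson's r was 0.55 (permutation p = 0.00607, adjusted p = 0.0364). Within array 1, rho was 0.59 (permutation p = 0.0805, adjusted p = 0.0966) and r was 0.72 (permutation p = 0.0211, adjusted p = 0.0633). Within array 2, rho was 0.42 (permutation p = 0.132, adjusted p = 0.132) and r was 0.57 (permutation p = 0.0347, adjusted p = 0.0694). Without the 2 chromosomes farthest from the median share, r was 0.44 and rho 0.30. The highest share not lit in both was 69.0%, on chromosome 18, and the lowest 34.0%, on chromosome 19. Their median log2 ratios over all probes were 0.23 and -0.09. The test cannot separate the relation from such an offset of the log ratios, which moves windows toward the threshold. Part of the difference between chromosomes may follow detection, but after adjustment the pooled r alone passed, and neither the pooled rho of 0.42 nor any relation within an array did.

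Longer probes were lit less often: 91.6% of probes of 44 to 45 bases on array 1 were lit in both channels, and 9.16% of probes of 60 bases, with 89.3% and 9.45% on array 2.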
